A study of Mus musculus with 15 samples.

How the data were processed

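RNA abundance was measured by poly-A selected, stranded RNA sequencing in 15 libraries of cultured mouse lymphatic endothelial cells, per the labels. The cells were Pdpn-positive, CD31-positive and CD45-negative cells from pooled lymph nodes. They were cultured with 0, 10 or 100 ng/mL of recombinant murine VEGF-C for 72 h. Groups and replicate letters A to E came from the sample titles, with 5 libraries per group.

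The authors deposited 1 table of 45706 Ensembl genes with an estimated count and an RPKM value for each library, per the file headers. The estimated counts deposited by the authors were fractional in 64.3% of values and summed to between 27784906 and 38590841 per library. The RPKM values deposited by the authors equalled the count divided by the listed gene length and by a library total that was 1.86 to 1.92 times the sum of the counts, and what this larger total holds is not given in the sources used here. The submitters' processing notes name FastQC, Bowtie2 and limma and the builds GRCm38 and mm10, without versions. The read counter, its use of strand, its treatment of reads that match several genes, and the annotation release are not given in the sources used here. A second deposited table held the 6719 genes with a median RPKM of at least 5, with the same values, and was not used. A length of 0 was listed for 977 genes.

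These choices can affect the values. Pseudogene models held 4.74 to 5.61% of the counts per library. With the treatment of reads that match several genes unknown, genes with near-identical copies and overlapping or antisense genes are uncertain. Of 65 named genes with a family member, 16 had a ratio to one that varied by under 15% over the libraries (coefficient of variation). Of these, 9 varied by no more than 30% themselves, among them Mcm6 with Mcm2 (ratio 3.7%), and 7 by more. The 7 were Lyz2 with Lyz1, Krt5 with Krt76, Fabp5 with Fabp5l2, H2-Q4 with H2-Q5, Gja1 with Gja6, Rcan1 with Rcan3 and Gata2 with Gata5, with coefficients of variation of the ratio of 2.0, 2.7, 4.3, 5.6, 9.5, 12.7 and 13.1%. Whether reads were shared or the genes moved together was not tested. In the annotation Acadvl, Bmp4, Crim1, Cxcl16, Dll4, Fdft1, Igfbp7, Itga9, Kbtbd11, Lpar1, Nid2, Reln, Tm7sf2 and Tmtc1 overlap another gene, so their values are uncertain too. Coordinates are those of GENCODE M21 on GRCm38, which held 45143 of the gene identifiers. The start positions in the deposited table lay 2 bases below these for 39399 genes.

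Estimated counts were rounded to whole numbers. Genes were kept by filterByExpr (17650 genes), libraries were scaled by TMM, and a quasi-likelihood model with group as its only term was fitted to all 15 libraries in edgeR 4.0.16 under R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Abundances are CPM (counts scaled to a common library size) with TMM scaling, given as mean ± SD over 5 libraries, and log2 fold changes carry their standard error. Precision rests on these 5 libraries. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No 2 libraries of a group agreed within counting noise, since the smallest chi-square per degree of freedom was 8.64.

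The comparisons, 33 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between the 5 libraries of either group. Predicted, unnamed and pseudogene models counted but were skipped, and 1 gene that the rule took is not reported here. It also took the called list members with the smallest p (2 per list for 100 ng/mL against unstimulated, 1 otherwise), 11 receptor and marker genes, and the 5 smallest p-values where no gene was called. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with the correlation between genes preset at 0.01, and again with an estimated correlation.

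The model was tested on simulated data with 200 changed genes, drawn from those with a mean of at least 1 CPM. Counts were drawn independently per gene and library. Of the unchanged genes 8 were called for 100 ng/mL and 4 for 10 ng/mL against unstimulated. For 100 ng/mL against unstimulated, over 17499 genes, it recovered 52% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes. For 10 ng/mL against unstimulated, over 17503 genes, it recovered 62% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes. Alternatives were DESeq2 1.42.0 size factors, library size alone, no filter, a filter of 10 CPM in 5 libraries, the DESeq2 Wald test, limma-voom, fits of only 10 libraries, a replicate block, stricter thresholds, limma on log2(RPKM + 1) and log2(RPKM + 0.1), and leaving out each library. Surrogate variables (sva 3.50.0, 3 variables) and the removal of 3 libraries were added after seeing the data.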

Results

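Transcript abundance was measured in lymph node lymphatic endothelial cells (LECs), the cells that line the lymphatic vessels and sinuses of the node. VEGF-C is the secreted growth factor that acts on these cells through the receptor Flt4. Cells were left unstimulated or were given 10 or 100 ng/mL of VEGF-C for 72 h, with 5 libraries in each group. Total estimated counts of unstimulated libraries A to E were 37132309, 33339438, 32097280, 32269338 and 35115606. Those of the 10 ng/mL libraries were 36172953, 33247069, 38590841, 35117405 and 35079844. Those of the 100 ng/mL libraries were 32972831, 29816335, 31085649, 27784906 and 35143292.

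The first principal component held 64.8% of the variance in log2 CPM and parted the 100 ng/mL libraries, at 38.8 to 78.5, from the other 10 libraries, at -41.8 to -22.7. Library B of the 100 ng/mL group stood apart from its group at 38.8, against 69.8 to 78.5 for the other 4. The second component held 12.6%. Unstimulated E, 10 ng/mL D and 100 ng/mL B had its lowest scores, at -41.1, -28.2 and -45.1.

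**Figure D1:**
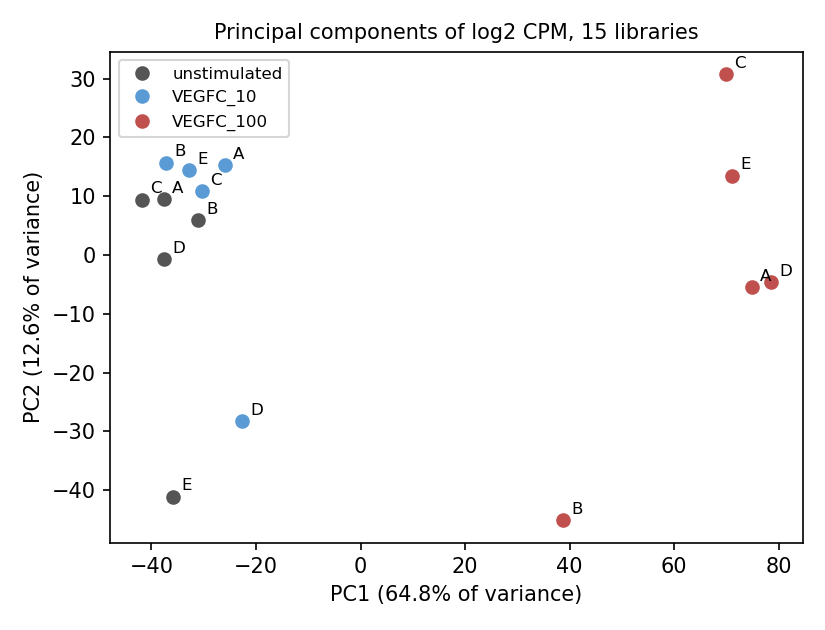
Scores of the 15 libraries on the first and second principal components of log2 CPM, coloured by group (VEGFC_10 and VEGFC_100 are the 10 and 100 ng/mL groups) and marked with the replicate letter. The 100 ng/mL libraries lie at 38.8 or above on the first component and all others at -22.7 or below.

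The receptors and cell markers were examined first in every group. The VEGF-C receptor gene Flt4 (ENSMUSG00000020357) rose from 614.9 ± 87.9 CPM (SD, n = 5) in unstimulated cells to 1576 ± 258 CPM at 100 ng/mL, a log2 fold change of 1.36 ± 0.12 (SE, adjusted p = 5.7e-07). Kdr, which encodes the other VEGF-C receptor, rose from 309.6 ± 62.8 to 964.7 ± 133 CPM (1.64 ± 0.14, adjusted p = 3.81e-07). The co-receptor gene Nrp2 rose from 447.3 ± 31.7 to 805.3 ± 252 CPM (0.85 ± 0.16, adjusted p = 0.000739). The hyaluronan receptor gene Lyve1 rose from 99.6 ± 50.9 to 803.8 ± 238 CPM (3.01 ± 0.38, adjusted p = 1.68e-05), and Cdh5, which encodes VE-cadherin, rose from 2162 ± 87.7 to 3450 ± 353 CPM (0.67 ± 0.07, adjusted p = 3.42e-06). Vegfc itself fell from 4.40 ± 0.92 to 2.16 ± 0.406 CPM (-1.02 ± 0.19, adjusted p = 0.000636). Pecam1, which encodes CD31, changed little, from 1587 ± 101.3 to 1806 ± 142 CPM (0.19 ± 0.07, adjusted p = 0.0354), and its call was lost under several alternatives, for example with library size alone (adjusted p = 0.0648, and between 0.0502 and 0.11 where it was lost).

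Flt1, Prox1 and Pdpn did not pass the test at 100 ng/mL. Prox1, the transcription factor of lymphatic identity, measured 242.5 ± 106 CPM in unstimulated and 477.7 ± 242 CPM in 100 ng/mL cells (adjusted p = 0.0599). It passed without library B of the 100 ng/mL group (log2 fold change 1.17, adjusted p = 0.0189). It also passed in the DESeq2 Wald test (adjusted p = 0.0343). Pdpn measured 101.9 ± 46.3 and 125.4 ± 26.8 CPM (adjusted p = 0.454, and 0.0296 without unstimulated E, 10 ng/mL D and 100 ng/mL B, an alternative chosen after seeing the data) and Flt1 231.1 ± 42.2 and 186 ± 36.4 CPM (adjusted p = 0.125). With surrogate variables, also added after seeing the data, each of them passed, Prox1 at 0.81 (adjusted p = 3.09e-06), Pdpn at 0.44 (0.0329) and Flt1 at -0.31 (0.00906) on the log2 scale. The model without them leaves out that unstimulated and 100 ng/mL libraries deviated together under different letters (correlations across genes of 0.216 to 0.559 in the best matching). The pan-leukocyte gene Ptprc was low in every group, at 4.47 ± 1.90 CPM in unstimulated, 4.11 ± 1.54 CPM in 10 ng/mL and 2.32 ± 0.595 CPM in 100 ng/mL cells. It fell at 100 ng/mL (-0.93 ± 0.31, adjusted p = 0.0234), a call lost without unstimulated C (adjusted p = 0.0727) or D (0.0629), or without 100 ng/mL C (0.0512) or D (0.0595), and with the replicate letter as a block (0.0603). At 10 ng/mL none of the 11 genes passed. Flt4 measured 702.9 ± 24.0, Kdr 397.6 ± 39.1, Nrp2 514 ± 28.8, Lyve1 137 ± 76.6, Cdh5 2274 ± 105, Pecam1 1691 ± 78.1, Prox1 278.2 ± 95.4, Pdpn 92.4 ± 38.4, Flt1 218.4 ± 44.1 and Vegfc 4.92 ± 1.37 CPM in this group.

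**Figure D2:**
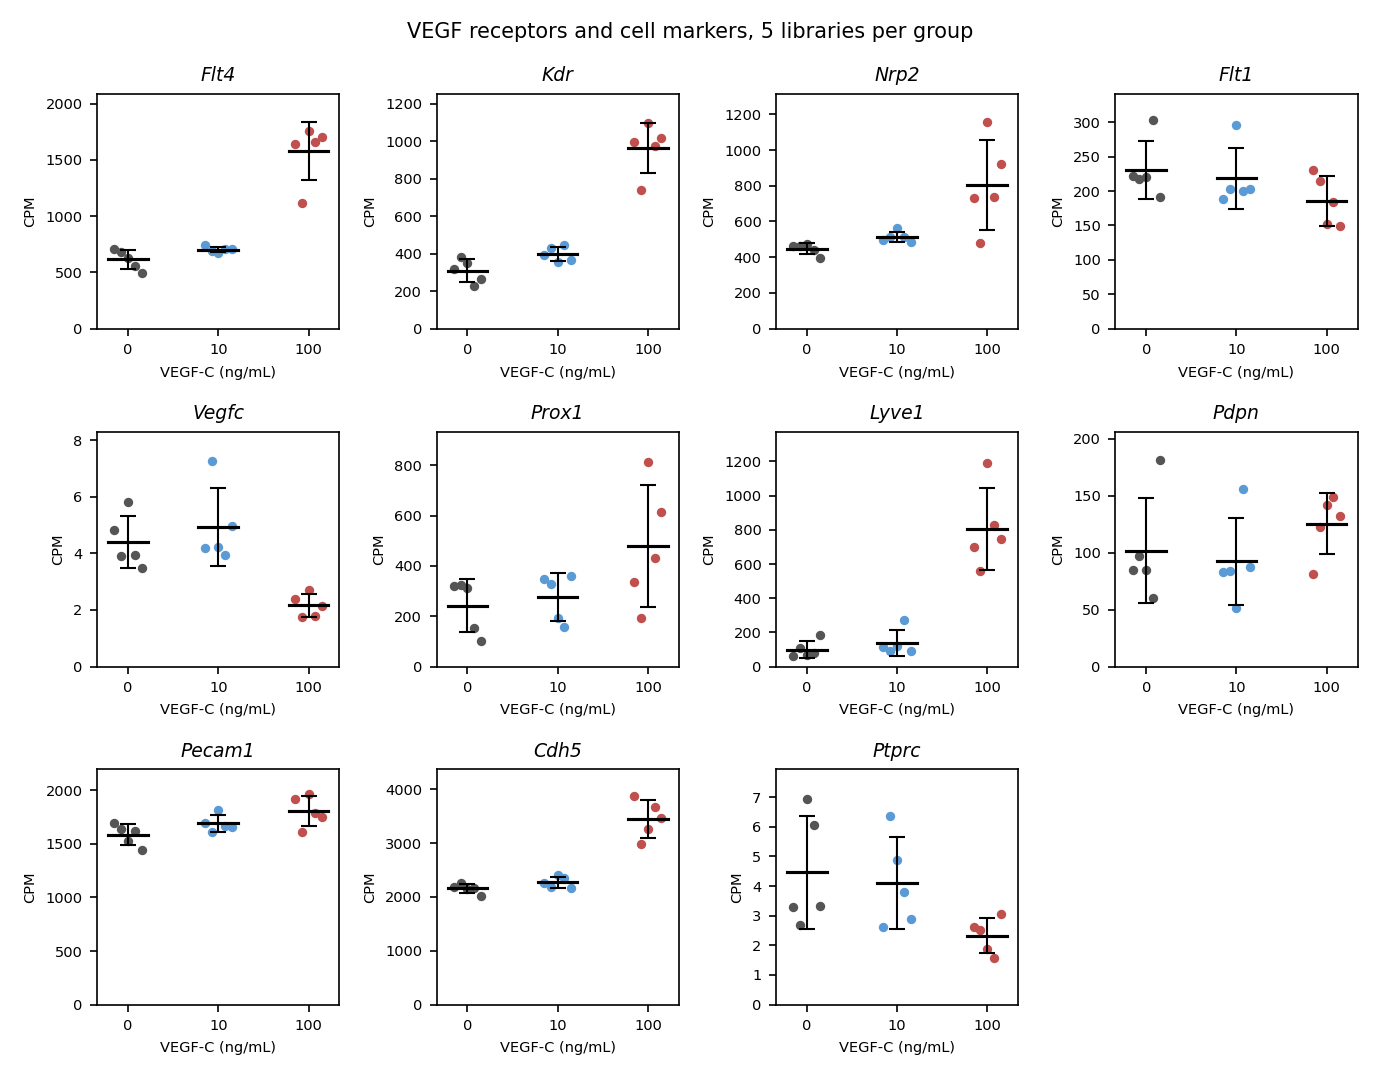
CPM of 11 receptor and marker genes by VEGF-C dose (points, 5 libraries per group, with the mean and SD). Flt4, Kdr and Lyve1 are highest at 100 ng/mL, and the 10 ng/mL means of Flt4 and Kdr are 702.9 and 397.6 CPM, against unstimulated means of 614.9 and 309.6 CPM.

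The comparison of 100 ng/mL with unstimulated cells asked which transcripts differed after 72 h of the higher dose. Abcc9 and Kcnj8, which encode the regulatory and pore-forming subunits of an ATP-sensitive potassium channel of vascular cells, rose from 0.230 ± 0.110 to 37.3 ± 18 CPM (log2 fold change 7.31 ± 0.48, adjusted p = 4.16e-08) and from 0.240 ± 0.130 to 27.6 ± 10.47 CPM (6.81 ± 0.42, adjusted p = 2.86e-08). Both are protein-coding genes on chromosome 6 of GRCm38, Kcnj8 (ENSMUSG00000030247) at 142564837 to 142571614 and Abcc9 (ENSMUSG00000030249) at 142587862 to 142702315. The potassium channel accessory subunit Kcne3 rose by 6.88 ± 0.37, the endothelin receptor gene Ednrb by 6.04 ± 0.46 and the chemokine receptor gene Cxcr4 (chromosome 1, 128588199 to 128592293) by 5.74 ± 0.24 on the log2 scale. Kbtbd11 rose by 6.18 ± 0.38, the metalloproteinase gene Mmp15 by 5.45 ± 0.46, and Reln, which encodes a secreted matrix glycoprotein, by 5.70 ± 0.79. Another of the largest rises was a gene model without a name. Reln varied widely among the stimulated libraries (22.7 ± 23.8 CPM).

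The largest falls were in C1qtnf7 (-5.60 ± 0.59), the collectin gene Colec11 (-5.21 ± 0.38), the lysophosphatidic acid receptor gene Lpar1 (-5.17 ± 0.41), the matricellular gene Smoc2 (-5.09 ± 0.51), Ptprq (-5.05 ± 0.62), the cadherin gene Cdh4 (-4.99 ± 0.68), Kank4 (-4.91 ± 0.34), Fmo1 (-4.89 ± 0.46), the growth factor gene Gdf6 (-4.81 ± 0.51) and Cbr2 (-4.78 ± 0.80). Adjusted p for these 10 lay between 6.25e-08 for Kank4 and 0.000209 for Cbr2. Colec11 measured 18.3 ± 4.67 CPM in unstimulated and 0.486 ± 0.389 CPM in 100 ng/mL cells, and Smoc2 69.5 ± 29.3 and 2.05 ± 1.58 CPM. In the same libraries 15 of 18 fibroblastic and mural markers fell. Whether these 10 falls came from fewer such cells was not tested. In all, edgeR called 7555 of 17650 genes, 3766 higher and 3789 lower, of which 710 and 1458 changed at least 2-fold. The 5 libraries of each group did not overlap for 27.2% of genes, where chance gives 0.79%.

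**Figure D3:**
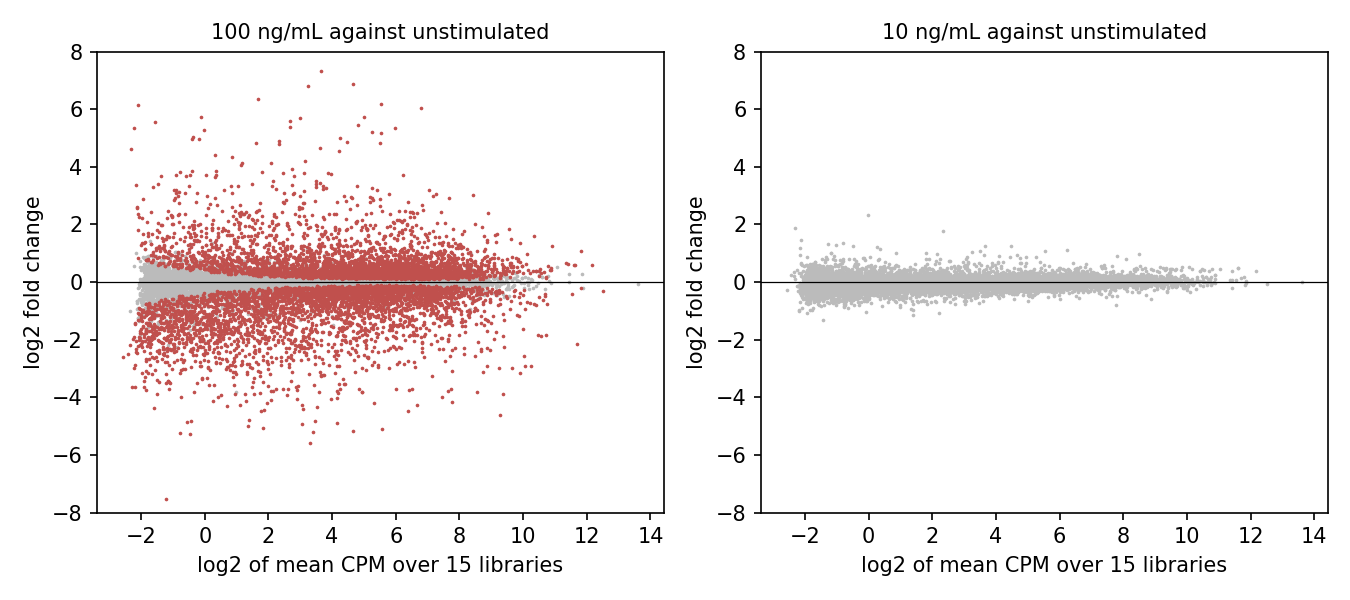
Log2 fold change against the log2 of the mean CPM over 15 libraries, for 17650 genes at 100 ng/mL (left) and 10 ng/mL (right) against unstimulated cells. Red points are the genes past an adjusted p of 0.05, which number 7555 on the left and 0 on the right.

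Genes of sprouting and tip cells, the leading cells of a growing vessel, rose as a group at 100 ng/mL. Of 20 tested, 11 rose and 2 fell, with the same counts adjusted over the list alone (camera, adjusted p = 0.000469 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.182). Cxcr4 and Kcne3 led this list. In the same libraries 15 of 18 fibroblastic and mural markers and 12 of 14 leukocyte markers fell, and 13 of 24 mitochondrially encoded and heat shock genes, a list for RNA quality and handling, rose. Among Notch genes, whose products pass signals between neighbouring cells, 10 of 19 rose and 4 fell, the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.149). The Notch ligand gene Dll4 rose from 28.5 ± 8.69 to 193.4 ± 56.2 CPM (2.76 ± 0.24, adjusted p = 5.31e-07) and Hes1 from 29.2 ± 2.06 to 61.0 ± 7.39 CPM (1.06 ± 0.09, adjusted p = 2.96e-07).

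Lymphatic and pan-endothelial lists moved in both directions. In the LEC identity list 8 of 23 rose and 7 fell (10 and 7 adjusted over the list alone, list adjusted p = 0.669). The integrin gene Itga9 rose from 16.1 ± 2.14 to 133 ± 43.6 CPM, while the transcription factor gene Gata2 fell from 117 ± 15.6 to 46.5 ± 5.83 CPM. Among pan-endothelial genes 11 of 20 rose and 6 fell (11 and 6 adjusted over the list alone, list adjusted p = 0.158), with Kdr and Icam2 (0.94 ± 0.09) leading. VEGF receptor and ligand genes gave 7 rises and 4 falls among 16 (7 and 4 adjusted over the list alone, adjusted p = 0.325), and the ligand gene Pgf rose from 41.0 ± 8.13 to 263 ± 47.0 CPM.

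In the MHC class I list, whose products load and present peptides to CD8 T cells, 18 of 23 fell and 0 rose (19 adjusted over the list alone), with a median log2 fold change of -0.55 (camera, adjusted p = 6.45e-09, and 0.182 with an estimated correlation). The peptide transporter gene Tap2 fell from 76.9 ± 3.43 to 45.8 ± 3.46 CPM and H2-Q4, whose ratio to H2-Q5 varied by 5.6% over the libraries, from 76.4 ± 11.5 to 27.8 ± 4.30 CPM. All 6 tested MHC class II genes fell (6 adjusted over the list alone, adjusted p = 0.00179, and 0.182 with an estimated correlation). These were low, as in H2-DMb1 at 0.442 ± 0.198 and 0.0965 ± 0.0462 CPM and Ifi30 at 8.96 ± 1.88 and 3.69 ± 1.45 CPM. Of 43 interferon-stimulated genes 33 fell and 1 rose (36 and 1 adjusted over the list alone, adjusted p = 9.53e-10, and 0.331 with an estimated correlation). The guanylate-binding protein gene Gbp5 fell from 107.4 ± 8.11 to 15 ± 4.72 CPM and the GTPase gene Iigp1 from 148.8 ± 14.4 to 52.7 ± 10.7 CPM.

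Among chemokine genes 8 of 16 fell and 0 rose (9 adjusted over the list alone, adjusted p = 0.00245, and 0.331 with an estimated correlation). Cxcl16 fell by 1.12 ± 0.15 on the log2 scale, and Cxcl12 fell from 162.1 ± 45.0 to 20.8 ± 26.5 CPM. Cytokine and colony-stimulating factor genes gave 13 falls and 2 rises among 24 (14 and 2 adjusted over the list alone, adjusted p = 0.000955, and 0.182 with an estimated correlation). The macrophage growth factor gene Csf1 fell from 1716 ± 136 to 228 ± 70.5 CPM and Bmp4 from 858 ± 117 to 109 ± 31.8 CPM. Of 21 NF-kB response genes 12 fell and 3 rose (13 and 3 adjusted over the list alone, adjusted p = 0.000487, and 0.182 with an estimated correlation), led by the adhesion molecule gene Icam1 (542.3 ± 28.2 to 195.2 ± 35.2 CPM) and the inhibitor gene Tnfaip3 (44.7 ± 7.71 to 12.6 ± 2.68 CPM). Leukocyte adhesion genes gave 15 falls and 7 rises among 29 (15 and 8 adjusted over the list alone, adjusted p = 0.0737, and 0.0355 without unstimulated E), led by Icam1 and Cd200 (-0.90 ± 0.08), and T cell co-signalling genes 7 falls and 4 rises among 21 (8 and 4 adjusted over the list alone, adjusted p = 0.758), with rises of Nos2 (3.10 ± 0.24) and Tgfb1 (1.58 ± 0.14).

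Leukocyte, fibroblastic and mural, and epithelial marker lists were lower in the same libraries as the MHC, interferon-stimulated, chemokine, cytokine, NF-kB and TGF-beta response lists. Some of these lists share members, so they are not separate counts. Acta2 is in both the fibroblastic and TGF-beta lists, and Tap1 in both the MHC class I and interferon-stimulated lists. Leukocyte markers fell in 12 of 14 cases (13 adjusted over the list alone, adjusted p = 0.000469, and 0.393 with an estimated correlation). They were low in unstimulated cells, with Lyz2, whose ratio to Lyz1 varied by 2.0% over the libraries, at 41.9 ± 17.8 CPM and Laptm5 at 13.7 ± 5.82 CPM. Fibroblastic and mural markers fell in 15 of 18 cases (16 adjusted over the list alone, adjusted p = 3.89e-06, and 0.211 with an estimated correlation), with Dcn, the decorin gene, falling from 759.6 ± 260 to 30.9 ± 18.3 CPM and the smooth muscle actin gene Acta2 from 299.9 ± 64.2 to 18.7 ± 16.7 CPM. Epithelial markers gave 6 falls and 1 rise among 9 (the same adjusted over the list alone, adjusted p = 0.017, and 0.275 with an estimated correlation), where Krt18 fell by 2.38 ± 0.31 and Krt5 rose by 0.96 ± 0.08. Blood endothelial markers gave 6 rises and 7 falls among 18 (6 and 8 adjusted over the list alone, adjusted p = 0.241), with Vwa1 at -2.79 ± 0.31 and the glucose transporter gene Slc2a1 at -1.01 ± 0.11.

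Of 25 cholesterol synthesis genes 24 fell and 0 rose (24 adjusted over the list alone), with a median of -1.01 (camera, adjusted p = 4.44e-13, and 0.182 with an estimated correlation). Fdft1, which encodes squalene synthase, fell from 33.5 ± 1.2 to 16.6 ± 1.39 CPM and Tm7sf2 from 4.57 ± 0.12 to 2.13 ± 0.23 CPM. YAP and TAZ target genes gave 15 falls and 3 rises among 22 (15 and 3 adjusted over the list alone, adjusted p = 8.39e-05, and 0.221 with an estimated correlation), led by Ajuba (-1.07 ± 0.08) and Crim1 (-1.83 ± 0.15). TGF-beta response genes gave 19 falls and 6 rises among 28 (19 and 7 adjusted over the list alone, adjusted p = 0.00179, and 0.275 with an estimated correlation), with Tgfbi at -2.44 ± 0.14 and Zeb1 at 0.70 ± 0.05. Unfolded protein and amino acid stress genes gave 11 falls and 2 rises among 25 (the same adjusted over the list alone, adjusted p = 0.00774, and 0.493 with an estimated correlation), with Slc3a2 at -0.91 ± 0.06 and Ppp1r15a at -0.55 ± 0.06. These 4 lists were lower in the same libraries as the fibroblastic and mural markers, of which 15 of 18 fell (median -1.998).

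Of 39 S phase genes 7 rose and 0 fell (3 adjusted over the list alone, adjusted p = 0.00833, and 0.804 with an estimated correlation). The list did not pass without unstimulated C (adjusted p = 0.0645). Over all genes 3766 of 17650 rose, so the share of S phase genes that rose was not raised. The estimated correlation between S phase genes was 0.825, far above the preset 0.01. The leading members of the list rose modestly, with Pcna at 0.39 ± 0.09 and Mcm6 at 0.37 ± 0.09. None of 41 genes of G2 and M phase passed in either direction, over all genes or adjusted over the list alone (list adjusted p = 0.641). Mitochondrially encoded and heat shock genes, a list for RNA quality and handling, gave 13 rises and 1 fall among 24 (16 and 1 adjusted over the list alone, adjusted p = 0.00774, and 0.493 with an estimated correlation), led by mt-Nd2 (675.6 ± 138 to 1110 ± 132 CPM) and mt-Rnr1 (0.68 ± 0.14).

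The remaining 9 lists did not pass (adjusted p from 0.0776 for basement membrane genes to 0.913 for integrins), and their rises and falls over all genes were as follows. Growth factor response genes gave 14 and 9 of 31 (Fos -3.00 ± 0.19, Rcan1 1.19 ± 0.10), p53 and cell cycle inhibitor genes 4 and 4 of 23 (Cdkn2b 1.18 ± 0.12, Cdkn1c -2.04 ± 0.27), endothelial junction genes 8 and 9 of 22 (Gja1 1.31 ± 0.09, Jup 1.08 ± 0.09), and basement membrane genes 8 and 16 of 35 (Nid2 3.07 ± 0.22, Igfbp7 -1.72 ± 0.12). Matrix protease genes gave 13 and 13 of 34 (Plau 1.85 ± 0.17), integrin genes 4 and 6 of 15 (Itga6 1.59 ± 0.11), fatty acid genes 7 and 8 of 25 (Fabp5 1.72 ± 0.18), glycolysis genes 2 and 4 of 20, and hypoxia response genes 6 and 11 of 24 (Hilpda 1.23 ± 0.11). Adjusted over the list alone these were 14 and 9, 3 and 4, 8 and 9, 10 and 18, 13 and 15, 4 and 6, 7 and 9, 2 and 4, and 7 and 12. The test was upward but the median and mean were negative for endothelial junction (median -0.083) and matrix protease genes (-0.218). The mean and the test differed in sign for growth factor response (mean -0.077), integrin (-0.011) and fatty acid genes (0.002), and the median and the test for glycolysis genes (0.002).

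**Figure D4:**
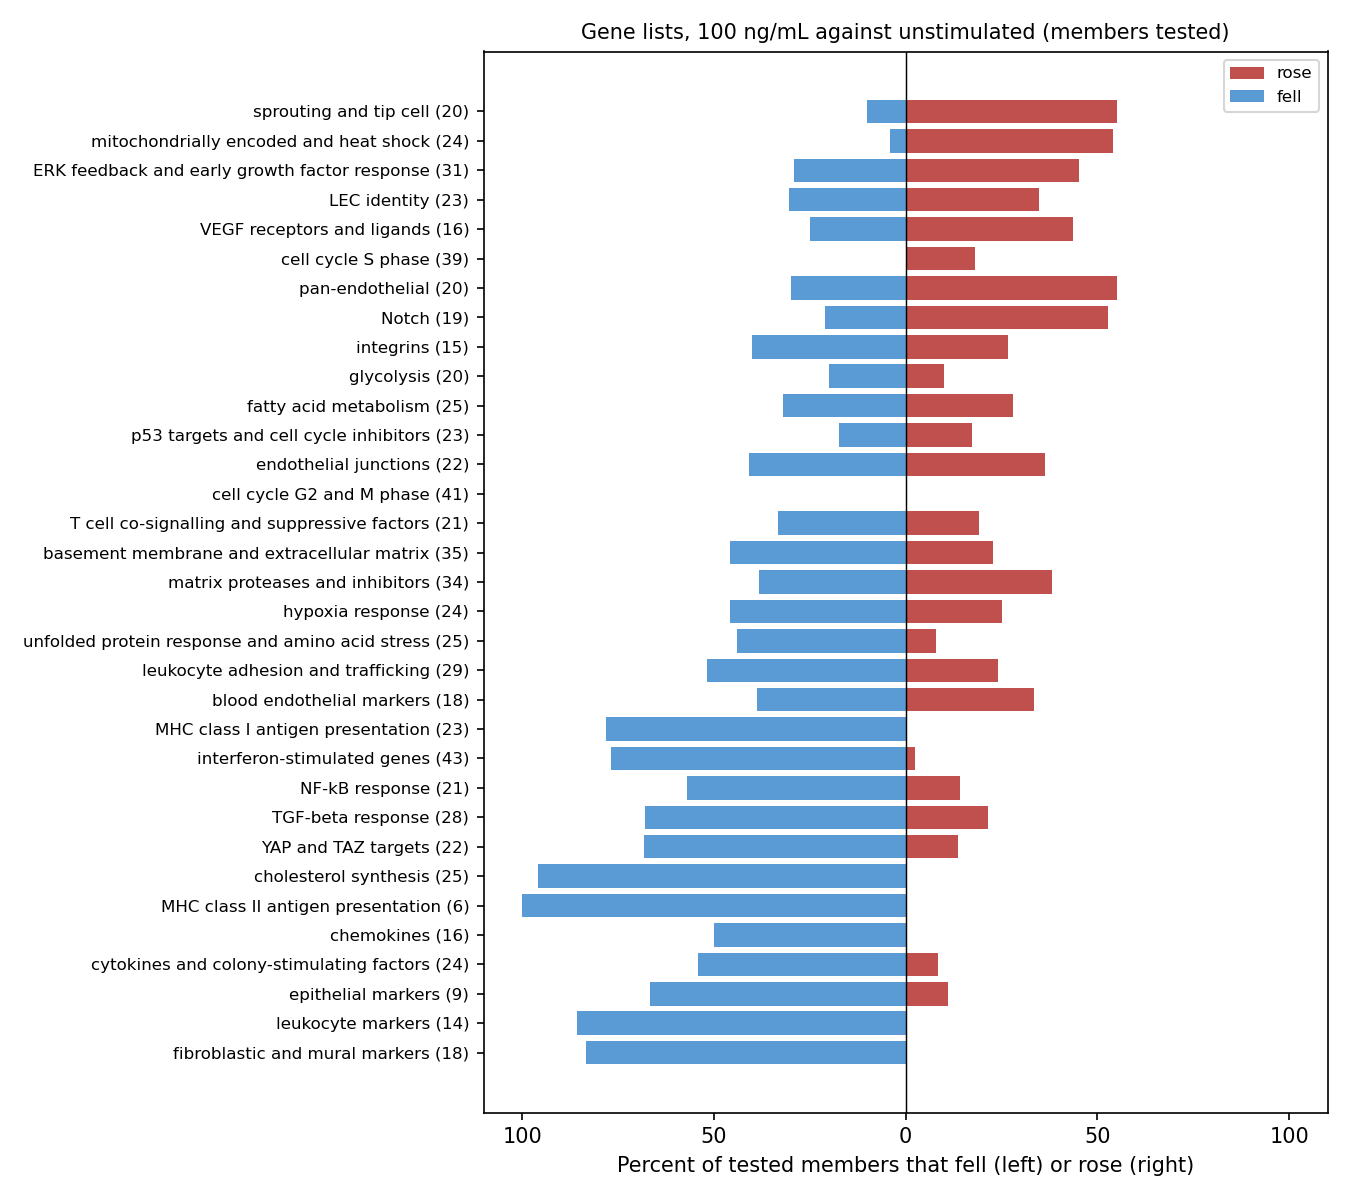
Percent of tested members of 33 gene lists that rose (red, right) or fell (blue, left) at 100 ng/mL against unstimulated cells, ordered by median fold change, with the number tested in parentheses. Of 25 cholesterol synthesis genes 24 fell, and of 20 sprouting and tip cell genes 11 rose.

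The comparison of 10 ng/mL with unstimulated cells asked the same of the lower dose. No gene passed in edgeR, 843 genes had an unadjusted p under 0.05 where 882 are expected by chance, limma-voom called 0 and the DESeq2 Wald test called 10. Leaving out each library moved the 843 to between 513 (without 10 ng/mL A) and 1637 (without 10 ng/mL D). A fit of only the 10 libraries compared called 0 of 17425 genes. It gave 1155 genes with an unadjusted p under 0.05 and a smallest adjusted p of 0.0689. The 5 libraries of each group did not overlap for 1.3% of genes, where chance gives 0.79%. The 5 smallest p-values belonged to Kcng2, the adaptor gene She, the Notch target Hes1, the myosin gene Myo7a and Dock4. All had an adjusted p of 0.97 in the edgeR fit of all 15 libraries. Kcng2 measured 1.78 ± 0.47 CPM against 0.805 ± 0.264 CPM, She 64.6 ± 9.18 against 41.8 ± 5.25 CPM, and Hes1 21.8 ± 2.11 against 29.2 ± 2.06 CPM. Myo7a measured 96.9 ± 4.90 against 64.2 ± 6.30 CPM and Dock4 298 ± 22.5 against 235.1 ± 26.9 CPM. All of these except Kcng2 passed in the DESeq2 Wald test (adjusted p = 0.0168 for She, Hes1 and Myo7a and 0.0492 for Dock4). With surrogate variables, added after seeing the data, 110 genes passed, 74 higher and 36 lower. In this model 4 of 100 divisions of the same libraries, the real one included, gave at least as many. Divisions other than the real one had a median of 0 but reached 723, so this count alone does not show changes. Libraries of the 2 groups deviated together under different letters (correlations across genes of 0.487 to 0.786 in the best matching), and the model without surrogate variables leaves this out, so that no gene passed does not show that none changed.

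At 10 ng/mL 8 of 33 lists passed with the preset correlation and 0 with an estimated one (adjusted p = 0.378 or above). No list member passed over all genes. The mitochondrially encoded and heat shock list was higher (median 0.39, adjusted p = 3.75e-13, and 0.378 with an estimated correlation), and 11 of its 24 members rose adjusted over the list alone. The other 7 were lower, namely G2 and M phase (median -0.27, adjusted p = 4.84e-11), interferon-stimulated (-0.14, 4.66e-06), S phase (-0.12, 0.00021), glycolysis (-0.15, 0.000663), leukocyte (-0.32, 0.019), unfolded protein (-0.09, 0.0338) and epithelial genes (-0.21, 0.0447), each with an adjusted p = 0.63 with an estimated correlation. Adjusted over the list alone, 1 Notch gene fell and no member of the other 31 lists passed. The number of lists past the threshold dropped to 5 without unstimulated C or without 10 ng/mL A, and rose to 11 without 10 ng/mL B. The mitochondrial and heat shock, G2 and M phase and interferon-stimulated lists passed without each of these 10 libraries. The leukocyte list did not without unstimulated C (adjusted p = 0.405) or 10 ng/mL A (0.179), D (0.143) or E (0.0827), nor the S phase list without unstimulated E (0.849) or 10 ng/mL B (0.0674), nor the glycolysis list without unstimulated E (0.0754). The unfolded protein and epithelial lists were also lost without single libraries (adjusted p up to 0.198 and 0.101). The mean and the median of fatty acid genes differed in sign (0.034 and -0.009), and YAP and TAZ targets had an upward test with a negative median (-0.005).

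The 2 doses were also compared directly. Most of the genes with the largest rises at 100 against 10 ng/mL were those named against unstimulated cells, with Abcc9 at 6.06 ± 0.43, Kcne3 at 5.93 ± 0.34, Kcnj8 at 5.75 ± 0.39, Ednrb at 5.54 ± 0.45, Reln at 5.39 ± 0.77, Cxcr4 at 5.39 ± 0.23 and Mmp15 at 5.28 ± 0.45. Stc1, which encodes the hormone stanniocalcin, rose from 3.67 ± 1 to 132.5 ± 39.8 CPM (5.17 ± 0.25, adjusted p = 1.54e-08). The largest falls included C1qtnf7 (-5.77 ± 0.59), Dcn (-5.09 ± 0.43), Smoc2 (-5.09 ± 0.51), Fmo1 (-4.96 ± 0.46), the protease gene Pappa (-4.88 ± 0.42), Lpar1 (-4.83 ± 0.40), Art4 (-4.78 ± 0.41), Colec11 (-4.70 ± 0.38), Tmtc1 (-4.66 ± 0.69) and the metalloproteinase gene Adamts18 (-4.64 ± 0.43). Flt4 rose by 1.17 ± 0.12, Kdr by 1.28 ± 0.14, Nrp2 by 0.65 ± 0.16, Lyve1 by 2.55 ± 0.37 and Cdh5 by 0.60 ± 0.07 against 10 ng/mL on the log2 scale. In all 7143 genes passed, 3509 higher and 3634 lower. Of the lists 15 of 33 passed with the preset correlation and 0 with an estimated one (adjusted p = 0.194 or above). Cholesterol synthesis genes again gave 24 falls among 25 (24 adjusted over the list alone, Fdft1 -1.01 ± 0.06), MHC class I genes 19 falls among 23 (19 adjusted over the list alone, Tap2 -0.67 ± 0.06), interferon-stimulated genes 27 falls and 2 rises among 43 (the same adjusted over the list alone, Gbp5 -2.87 ± 0.16), and sprouting genes 12 rises and 3 falls among 20 (the same adjusted over the list alone). With an estimated correlation the adjusted p was 0.194 for the cholesterol, MHC class I and sprouting lists and 0.473 for interferon-stimulated genes. Fibroblastic and leukocyte markers fell in 14 of 18 and 10 of 14 cases (15 and 13 adjusted over the list alone, adjusted p = 0.225 and 0.529 with an estimated correlation). Dcn, among the largest falls, belongs to the fibroblastic list. Whether the largest falls came from fewer fibroblastic cells was not tested. Of the mitochondrially encoded and heat shock genes 1 rose and 2 fell among 24 (0 adjusted over the list alone, list adjusted p = 0.91).

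Fold changes of the 2 doses against unstimulated cells were then compared across genes, which are not independent replicates. Their Pearson correlation was 0.408. Simulated groups with no change at either dose gave 0.495 through the shared unstimulated libraries (range 0.471 to 0.523 over 50 simulations). The real 100 ng/mL group had 7555 called genes. Their changes widen the spread of its fold changes and lower the correlation, so 0.408 and 0.495 cannot be compared. The covariance was 0.0597, above the simulated 0.0199 (0.0184 to 0.0217), a difference of 0.0398. Each gene was simulated on its own, while the real libraries deviated together across genes, so the simulated ranges are too narrow. With the unstimulated libraries split between the doses the correlation averaged 0.213 (0.0663 to 0.347 over 20 divisions) and the covariance 0.0387. It was 0.252 without 10 ng/mL D. Of the 7555 genes called at 100 ng/mL, 67.4% had the same direction at 10 ng/mL. With split controls the share averaged 64.7% (57.1 to 71.8% over 20 divisions). The simulations gave 66.6%, but they held no change at 100 ng/mL, so their share is no reference for genes called there. No gene was called at both doses, since none was called at 10 ng/mL.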

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

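The tests of a feature shared by 3 libraries, of depth, of surrogate variables and of matching libraries were chosen only after the results were seen. The tests on slopes were fixed before their values were seen, but after the tests on CPM lost had fallen between their bounds.

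In 48 of 396 groups of 5 libraries 1 library lay far from the other 4, where chance gives about 1 in 20. Of these, 6 were in unstimulated E, 15 in 10 ng/mL D and 13 in 100 ng/mL B. Unstimulated E was high for Rcan1 (41.6 CPM) and low for Csf1 (1480 CPM, against 1740 to 1820 in the others) and Cd200 (211 CPM). Its mean log2 CPM was 8.51 over pan-endothelial, 7.66 over endothelial junction and 6.76 over unfolded protein genes, against 8.67 to 8.70, 7.84 to 7.89 and 6.57 to 6.62 in the others. Unstimulated D was high for Ptprq (14 CPM), Plau (499 CPM) and Flt1 (303 CPM).

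Library D of the 10 ng/mL group was low for Fmo1 (8.79 CPM, against 30.4 to 33.3), Pappa (3.05 CPM), Art4 (1.99 CPM), Bmp4 (623 CPM), Csf1 (1140 CPM, against 1750 to 1860), Igfbp7 (533 CPM), Crim1 (1510 CPM), Tm7sf2 (3.98 CPM) and Dnajb1 (65.1 CPM). It was high for Rcan1 (40.6 CPM), Gja1 (232 CPM), Aldoc (3.28 CPM) and Lyve1 (272 CPM, against 89.5 to 119). Its mean log2 CPM was 3.69 over T cell co-signalling and 7.77 over endothelial junction genes. Library C was high for Ptprq (6.86 CPM), Flt1 (297 CPM) and pan-endothelial genes (8.84), and library E low for Myo7a (88.3 CPM).

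Library B of the 100 ng/mL group was high for genes that fell, namely Lpar1 (2.77 CPM), Smoc2 (4.77 CPM), Gdf6 (2.47 CPM, against 0.219 to 0.328), Acta2 (47.9 CPM), Krt18 (31.3 CPM), Cxcl12 (67.4 CPM, against 5.24 to 17.7) and Bmp4 (164 CPM). It was low for Myo7a (226 CPM), Fabp5 (59.9 CPM) and Flt4 (1120 CPM, against 1640 to 1760). Its mean log2 CPM was 1.48 over epithelial, 2.11 over cytokine and 5.39 over hypoxia genes. Library C was high for Cdkn1c (2.26 CPM), Gbp5 (23.3 CPM) and Iigp1 (71.0 CPM) and low for Dnajb1 (55.6 CPM). Library A was low for mt-Nd2 (882 CPM), and library D was high for mt-Rnr1 (223 CPM) and low for leukocyte adhesion genes (5.08).

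The weaker response of 100 ng/mL B was weighed first. Its total of 29.816 M counts argues against low depth, since library D, with a full response, had 27.785 M counts. Mixed-in unstimulated RNA would keep equal shares of rises and falls, but B kept a median of 0.551 of the rises and 0.783 of the falls, a difference of -0.232 against -0.0817 to 0.0684 in the other 4 libraries (tested only against the unstimulated mean). The smaller correlation of B's deviations with those of unstimulated E and 10 ng/mL D across genes was 0.428. These libraries were chosen after seeing the data and had the lowest scores on the second component, so a positive correlation was likely in advance. It cannot show that a shared feature weakened the response. What such a feature would be was not tested, and a biological difference between cultures stays open.

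The fall of MHC class I and interferon-stimulated genes at 100 ng/mL came with falls of leukocyte and of fibroblastic and mural markers. The CD45-negative sort would remove leukocytes. The most abundant markers in unstimulated cells were Lyz2 and Laptm5 (41.9 and 13.7 CPM) among the leukocyte genes named and Dcn (759.6 CPM) among 4 matrix genes. The CPM lost over leukocyte markers was 0.0321 of that lost over the MHC class I list, and that lost over Col1a1, Col1a2, Col3a1 and Dcn 0.808 of it, values that alone left both explanations open. Within the other 10 libraries, the MHC class I total had a slope of -1.67 on the leukocyte total (-2.62 to 0.874 leaving out each library), where the fall needs 31.1. On the matrix total the slope was -0.25 (-0.42 to -0.136), where it needs 1.24. The interferon-stimulated total, with no bound fixed beforehand, had a slope of -4.87 on the leukocyte total (-6.66 to 0.144), where the fall needs 37.5. On the matrix total it was -0.556 (-0.706 to -0.34), where 1.49 is needed. The 10 libraries deviated together in pairs across groups, so these ranges may understate the uncertainty. The slopes argue against fewer leukocytes or fibroblastic cells as the whole cause, and a response of the endothelial cells to VEGF-C remains a hypothesis.

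Other divisions of the 10 libraries into 5 and 5 were fitted, 100 of 126 per comparison. For 100 ng/mL against unstimulated cells 1 of 100, the real one, gave 7555 genes (highest other 2272), and against 10 ng/mL 1 of 100 gave 7143 (highest other 1460). Such counts are unlikely from a chance division of these libraries, though a share below 1 of 100 could not be reached. Libraries were taken as separate units, so chance differences between cultures or preparations were not tested. For 10 ng/mL against unstimulated cells 100 of 100 gave as many as the 0 called (highest other 4), which a count of 0 fixes in advance. With surrogate variables 4 of 100 divisions, the real one included, gave at least the real count of 110 genes. Divisions other than the real one had a median of 0. The highest of the 4 gave 723, which points to a structure of the samples.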

How the results depend on the processing

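Surrogate variables and the removal of unstimulated E, 10 ng/mL D and 100 ng/mL B were chosen after seeing the data. No alternative turned the direction of a called gene or list. Genes called at 100 ng/mL against unstimulated cells (7555) fell to 2168 with a 2-fold minimum and to 4961 with the stricter filter, which tests fewer genes (10373), and ranged from 5416 to 10253 elsewhere. Leaving out each library gave 6750 to 7863. Against 10 ng/mL, 7143 became 1940 with a 2-fold minimum and 6240 to 7562 leaving out each library. The count of 0 at 10 ng/mL became 10 with the DESeq2 Wald test and 110 with surrogate variables, with the cause not tested, and 0 to 0 leaving out each library. Without the 3 libraries the counts were 8234, 0 and 8101.

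With an estimated correlation 0 lists passed in each comparison, against 16, 8 and 15. Leaving out each library gave 15 to 17, 5 to 11 and 13 to 16. The correlation of the 2 doses was 0.213 with split controls, and 0.252 to 0.45 leaving out each library.

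The replicate letters share only a letter. Same-letter libraries correlated at -0.342 to 0.132 and 0 libraries correlated best with their own letter. With the letter as a block the counts were 7049, 0 and 6566 genes, 16, 8 and 13 lists, and a correlation of 0.413. Of the genes named, 2009 of 2052 values at 100 ng/mL, 361 of 377 at 10 ng/mL and 1365 of 1392 between doses kept their direction and side of the threshold. Depth limits genes near 0.1 CPM, where a library of 27784906 counts holds few counts.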

Other observations

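The tests of surrogate variables and of matching libraries were chosen only after the results were seen, and the families below were grouped by symbol after the data were examined.

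Of 350 families of genes with a shared symbol stem, 17 passed camera at 100 ng/mL against unstimulated cells with the preset correlation and 0 with an estimated one. All 12 pregnancy-specific glycoprotein (Psg) genes rose by 2.29 to 2.47 on the log2 scale, with Psg22 going from 13.3 ± 2.55 to 69.1 ± 15.7 CPM (SD, n = 5, list adjusted p = 2.43e-10, and 0.906 with an estimated correlation). Their ratios to Psg22 varied by only 3.8 to 9.0% over the libraries while Psg22 itself varied by 83.2%, so these are uncertain as separate genes. All 8 Serpina3 protease inhibitor genes tested as a family fell (adjusted p = 1.45e-08, and 0.906 with an estimated correlation), Serpina3g from 142 ± 4.74 to 7.35 ± 4.15 CPM. Their ratios to Serpina3g varied by 8.3 to 32.3% while Serpina3g varied by 68.4%, so these too are uncertain as separate genes. Of 13 sodium channel (Scn) genes 10 rose (adjusted p = 0.00845, and 0.921 with an estimated correlation), with Scn3a going from 155 ± 73.8 to 627 ± 262 CPM. Scn1a, Scn2a1 and Scn9a kept ratios to Scn3a within 8.0 to 8.5%. Of 19 C-type lectin (Clec) genes 17 fell and 0 rose (adjusted p = 5.73e-05, and 0.906 with an estimated correlation), and of 8 Gimap genes 6 rose and 1 fell (adjusted p = 0.0263, and 0.906 with an estimated correlation). Leukocyte markers fell in the same libraries as these families changed (12 of 14, median -1.605), as did fibroblastic and mural markers (15 of 18).

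Libraries of different letters deviated together. The best matching between each pair of groups, found alone, closed into 5 of 5 sets, on odd and on even chromosomes too. Independent matchings would close with a probability of 0.00833, but these were taken from the same libraries and were not independent. The closing therefore cannot tell shared cultures from variation common to separate ones. Correlations within the sets ran from 0.21 to 0.786. Cultures or a preparation shared across groups under other letters is a candidate explanation, which the labels do not address. Variation between cultures that the group means leave out may also hide changes at 10 ng/mL. With 3 surrogate variables 110 genes passed, but 4 of 100 divisions of the libraries, the real one included, gave at least as many. The highest of these 4 gave 723, so this count does not show such changes. Fold changes of the 2 doses had a covariance of 0.0597, above the highest of 0.0217 simulated for shared unstimulated libraries. Each gene was simulated on its own, while the real libraries deviated together across genes, so the simulated range cannot decide its source. With split controls, where the doses shared no unstimulated library, the covariance averaged 0.0387 and was positive in all 20 divisions (0.0144 to 0.0635). The divisions reuse the same libraries, which deviated together, so the source of this remainder stays open. The correlation of 0.408 and the 67.4% of genes with the same direction cannot be set against the simulated 0.471 to 0.523 and 65.1 to 68.1%. The simulations held no change at 100 ng/mL, where 7555 genes were called.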
